A study of Mus musculus with 10 samples.

How the data were processed

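Messenger RNA was sequenced from mouse CD8+ T cells of adults aged 2 to 4 months and of neonates aged 6 to 8 days. The thymus libraries came from CD8 single positive thymocytes, depleted magnetically of CD4+ cells and then sorted on CD8. The naive and innate memory libraries came from splenic CD8-selected cells sorted as CD44low CD122low and as CD44high CD122high. Each age and compartment gave 1 library. Small RNA was sequenced from splenic CD8+ T cells of irradiated adult mice that had received gBT-I bone marrow, either wild type (control) or carrying an inducible human Lin28b gene (iLin28b), with doxycycline in the drinking water. Each of these groups was 1 sample, counted in 2 columns named A and B. Columns A and B were treated as repeat measurements of 1 sample, since what separates them is not given in the sources used here.

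The mRNA values were the authors' deposited FPKM for 8 conditions, made with TopHat2 2.1.1 and Cuffdiff 2.2.1 on the mm9 genome per the submitters' processing notes. The same table held the authors' p-value and q-value for each of 28 comparisons. Those calls are quoted as the authors' and were not recomputed, and how Cuffdiff modelled spread with 1 library per condition is not given in the sources used here. For small RNA the authors deposited, per miRNA precursor, the read count and the normalised read count (RPM) of each column. Those reads had been trimmed with cutadapt 1.8.3 and aligned with Bowtie, whose version is not given in the sources used here, per the submitters' processing notes. Gene symbols and positions are those of the deposited table.

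Of the 8 mRNA conditions, 6 were used. The thymus conditions were matched to samples by tissue and age, and those named low and high by the sort gate in the labels. The naive values are thus those of the low conditions, in which Cd44 was at 3.13 (adult) and 6.00 (neonatal) FPKM, against 36.0 and 34.4 in the high ones. The remaining 2 conditions have the word naive in their names, as do the titles of the samples matched to low. That leaves a doubt over the match, and these 2 conditions were not used here. The bulk spleen comparisons that had been set out (4 results) were therefore not made, and the limma fit set out for 8 libraries and 4 compartments was made with 6 and 3. Naive spleen against thymus was compared in their place, a choice made after the data were seen. From 23951 genes, 1 gene that the authors' program had set aside for high depth and 3 genes whose FPKM differed between comparisons were left out. Values came as FPKM, so the read depth per mRNA library, and with it the counting error of a gene, could not be computed. In each library between 8014 and 8225 genes reached FPKM 5. The upper quartile of FPKM lay between 11.6 and 11.9 in the 6 libraries.

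Unless named otherwise, differences are of log2(FPKM + 1). With 1 library per group, no comparison of 2 libraries had a replicate to check it against and none was given a p-value. A gene was counted by size when its FPKM + 1 differed 2-fold or more and its FPKM was 5 or more in 1 of the libraries compared. A gene that passes through 1 library alone can thus only be higher in that library, which holds for list members as well. The genes the text names are the 8 largest differences per direction, the 10 largest per direction shared by the 3 compartments, the 2 to 4 largest members of each list, and Lin28b, Dntt, Cd44, Il2rb and Eomes. Predicted genes, small RNA genes, antigen receptor segments and symbols ending in Rik were counted but not named, apart from Mir719, Mir703 and 5830411N06Rik, which were chosen after their values were seen, and some genes that the rule names are not reported here. These choices, the lists and the tests were made before the data were examined. Exceptions are the naive spleen against thymus comparison, the set tests, the differences of list medians between compartments, the tests of explanations other than the count over splits, the leaving out of small RNA genes, the innate memory marker genes defined in neonatal cells, the let-7 family without let-7c-5p and the genes said to have been chosen later.

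There were 20 fixed gene lists. They were fetal-type genes and let-7 targets, naive T cell genes, memory T cell genes, cytotoxic effector genes, effector and memory transcription factors, innate cytokine and killer receptors, cell cycle genes, immature thymocyte genes, and T cell exit and maturation genes. The others were interferon-stimulated genes, glycolysis genes, oxidative phosphorylation genes, immediate early and stress genes, B cell markers, myeloid and dendritic cell markers, erythroid markers, CD4 and regulatory T cell markers, natural killer and gamma-delta T cell markers, CD8 T cell identity genes and sex-linked genes. Some genes are on more than 1 list, such as Il2rb, Klf2 and Blk. The median difference of a list's members at FPKM 5 or more was set beside 10000 random lists of the same size, matched on mean expression in 20 bins. The range given for the random lists is their central 95%. This range describes 2 libraries and their genes, not animals. Lists with fewer than 3 members at FPKM 5 were given no median.

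Across compartments, limma 3.58.1 (R 4.3.3) was fitted to log2(FPKM + 1) with age and compartment as additive terms over the 6 libraries. The fit used empirical Bayes moderation with a trend and 8645 genes at FPKM 5 or more in at least 2 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, all tests two-sided. The residual of this fit, with 2 degrees of freedom and a prior of 3.12, is the variation of the age difference between compartments and not variation between animals. Lists were compared with the other genes by camera with a preset correlation of 0.01 and again with an estimated correlation. The latter rests on the 2 residual degrees of freedom and has little power, so a list that fails there is shown neither changed nor unchanged. Tested on simulated data for the age effect over 8645 genes with 200 changed, the fit recovered 98% of genes changed by 1 on the log2 scale. It made 8 false calls among 206. The simulated genes took their spread from the fitted trend alone, without the differences in spread between genes that the data hold. These values therefore do not give the recovery or the false calls in the data. The rule of size, tested on 8168 simulated genes for the age difference in naive cells with 200 changed 4-fold, recovered 100% and called 2 unchanged genes.

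Mature miRNAs took the value of their highest precursor entry, since several precursors share reads, which reduced 2061 entries to 1915 mature miRNAs. Columns A and B were summed and scaled to RPM of these collapsed reads, 1352086 for iLin28b and 609393 for control. A count of 3, the floor, stood for 2.22 RPM in iLin28b and 4.92 RPM in control. The 241 miRNAs with 50 or more reads over both samples were compared. Ratios carry exact conditional binomial 95% intervals, which hold counting error alone, and the range over the 4 pairings of the A and B columns. Between A and B the median absolute log2 difference was 0.34 in iLin28b and 0.25 in control, and the chi-squared per degree of freedom was 70.5 and 12.7, so that counting error understates the spread. The lists were the let-7 family, the miR-17-92 cluster with its paralogs, and T cell miRNAs. On simulated counts of 241 miRNAs, the intervals covered the true ratio in 95.0% of cases. Those counts held counting error alone, so this coverage does not carry over to the data.

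Alternatives tried were other pseudocounts and FPKM minimums, median-centred values, TPM, a fit without trend, leaving out each compartment, other read minimums, other scalings of the miRNA reads, and the sum over precursor entries. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining computing.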

Results

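The comparisons asked how CD8+ T cells of neonatal mice differ in their mRNA from those of adults, in the thymus, in naive spleen cells and in innate memory cells, and which miRNAs differ when Lin28b is switched on in adult CD8+ T cells. There were 6 mRNA libraries and 2 small RNA samples, 1 per group, so no comparison of 2 libraries could be checked against replicates. Sizes are differences of log2(FPKM + 1), neonatal minus adult unless named otherwise. Calls by Cuffdiff are quoted from the authors' deposited table and are theirs.

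Across thymus, naive and innate memory cells, neonatal CD8+ T cells had higher mRNA of the fetal-type RNA-binding protein Igf2bp3, of cell cycle genes (23 of 34) and of some memory T cell genes (9 of 27). They had lower mRNA of some naive T cell genes (5 of 20) and T cell exit and maturation genes (3 of 25). Igf2bp3, a let-7 target bound up with fetal growth, rose by 3.66 on the log2 scale (SE 0.20, adjusted p = 0.0237 by limma, higher in 3 of 3 compartments). S100a4, a calcium-binding protein of memory T cells, rose by 3.91 (SE 0.50, adjusted p = 0.0302, higher in 3 of 3). The chromatin remodeller Chd3 fell by 2.93 (SE 0.33, adjusted p = 0.0284), Als2cl fell by 3.02 (SE 0.24, adjusted p = 0.0280), and Il6st, the signalling chain of the interleukin-6 receptor, fell by 1.96 (SE 0.19, adjusted p = 0.0280), each lower in 3 of 3. Lin28b, which blocks let-7 maturation, was too low to be tested. It was listed at 0 in adult thymus and adult naive cells and at 0.0127 FPKM in adult innate memory cells, against 0.438, 1.40 and 1.63 FPKM in the neonatal libraries.

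Limma called 552 of 8645 genes for age, 348 higher and 204 lower in neonatal cells. The spread behind these calls is that of the age difference between compartments, not between animals. The count was 341 without the thymus, 9 without the naive and 71 without the innate memory compartment. These fits had 4 libraries each and fewer residual degrees of freedom, so a fall need not come from the compartment left out. At an unadjusted p under 0.05 by limma they had 2639, 1560 and 1602 genes, against 2626 with all 6 libraries. The count of called genes was 348 without a trend and 0 with no filter on low values (3082 at an unadjusted p under 0.05). The smallest adjusted p was 0.00396, for Mir719, whose short transcript is measured with little certainty by FPKM.

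Among the lists, 23 of 34 cell cycle genes rose with neonatal age over all genes tested and 34 when adjusted over the list alone. Examples, chosen after their values were seen, are Ccnb2 (2.40), Birc5 (2.58), Mki67 (2.22) and Rrm2 (2.35). Memory T cell genes had 9 of 27 higher, and 14 adjusted over the list alone, among them Ccr2 (2.18), Ccl3 (1.97) and Bhlhe40 (1.77). In naive cells Ccr2 was at 0 (adult) and 1.43 (neonatal) FPKM, Ccl3 at 0 and 1.47 and Bhlhe40 at 0.898 and 4.06. These values lie under FPKM 5, so the naive part of their rise rests on low levels. Naive T cell genes had 5 of 20 lower, and 11 adjusted over the list alone, with the transcription factor Lef1 at -0.68. T cell exit and maturation genes had 3 of 25 lower, and 10 lower with 1 higher adjusted over the list alone. Interferon-stimulated genes had 3 of 25 lower, namely Dhx58 (-1.42), Oas3 (-1.09) and Trim30a (-0.70), and 8 adjusted over the list alone. Oxidative phosphorylation genes had 4 of 27 higher, namely Cox6c (0.81), Cox5b (0.74), Ndufa1 (0.74) and Ndufb5 (0.53), and 12 adjusted over the list alone. Those last 7 genes and Lef1 were named after their values were seen.

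Fetal-type genes and let-7 targets had 2 of 14 higher, Igf2bp3 and the B-lineage transcription factor Arid3a (1.70), and 5 higher with 1 lower adjusted over the list alone. Glycolysis genes had 2 of 16 higher and 1 lower, the enzyme Tpi1 at 1.48, Pkm at 0.55 and Pdk1 at -0.58, and 4 higher with 1 lower adjusted over the list alone. Cytotoxic effector genes moved both ways, with Ifng (1.76) higher and the pore-forming protein Prf1 (-1.60) lower of 16. Adjusted over the list alone there were 2 higher and 1 lower. Innate cytokine and killer receptors had 1 of 16 lower, Tlr1 (-1.42), and 6 higher with 2 lower adjusted over the list alone. Immediate early and stress genes had 1 of 20 lower, Hspa1b (-2.24), and 1 higher with 2 lower adjusted over the list alone. Effector and memory transcription factors and immature thymocyte genes had 0 calls by limma over all genes, and adjusted over the list alone 1 higher with 2 lower of 18, and 2 higher with 2 lower of 20. At an unadjusted p under 0.05 there were 2 higher with 3 lower and 3 higher with 4 lower. Genes outside the naming rule in these sentences were chosen after their values were seen.

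Genes that miss the threshold included the scavenger receptor Cd163l1 at 4.83 (SE 0.98, adjusted p = 0.0549), the T-bet gene Tbx21 at 2.29 (adjusted p = 0.0680), Eomes at 1.01 (adjusted p = 0.209), Cd44 at 0.52 (adjusted p = 0.170) and Il2rb at -0.05 (adjusted p = 0.825). By camera with a preset correlation, 9 of the lists differed from the other genes. The 6 with the smallest adjusted p were cell cycle (adjusted p = 3.97e-18), interferon-stimulated (2.45e-08), oxidative phosphorylation (4.05e-08), naive (1.19e-07), exit and maturation (6.69e-06) and memory genes (8.48e-06). None of the lists passed with an estimated correlation, where cell cycle, naive and exit genes had adjusted p = 0.482 with an estimated correlation. With 2 residual degrees of freedom that setting had little power, so it does not decide whether these lists changed. Among marker lists, natural killer and gamma-delta markers had 0 of 6 called by limma, 4 higher adjusted over the list alone and 4 higher unadjusted. CD8 identity genes had 0 of 17 called, 0 adjusted over the list alone, and 1 higher with 7 lower unadjusted. Sex-linked genes had 1 of 4 lower, Ddx3y (-0.84), and 3 adjusted over the list alone. The sex of the animals did not enter the fit, so a differing sex make-up of the ages could not be told apart from age. Myeloid markers had Itgax (1.65) higher and Ctss (-0.77) lower of 3, the same counts adjusted over the list alone. These 3 genes were chosen after their values were seen. B cell and CD4 markers had 0 of 5 and 0 of 6 called, 1 higher and 0 adjusted over the list alone, and 1 higher, and 1 higher with 2 lower, unadjusted.

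A 2-fold or larger age difference in the same direction in all 3 compartments was found for 92 of 7883 genes, 55 higher and 37 lower. The count was 42 with a pseudocount of 5 and 171 with a minimum FPKM of 1. The other 3 patterns of sign gave 9, 4 and 5 genes. Besides the genes above, the higher group held the linker histone H1f0, Tspan4, Tmem176b, Cd163l1, Ube2c and Cdca8. The lower group held Fgf13, Insl6, BC094916, H2-DMa, H2-Q9, Pydc4 and Mid1, of which H2-Q9 has close paralogs that share reads. Across genes, the age differences correlated with r = 0.49 between thymus and naive cells, 0.36 between thymus and innate memory cells and 0.49 between naive and innate memory cells, although genes are not independent replicates. Compartment accounted for 56.6% of the variance over 8645 genes, age for 27.1% and the remainder for 16.3%. Compartment had 3 levels and age 2, so their shares have unlike degrees of freedom and do not rank compartment above age.

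**Figure D1:**
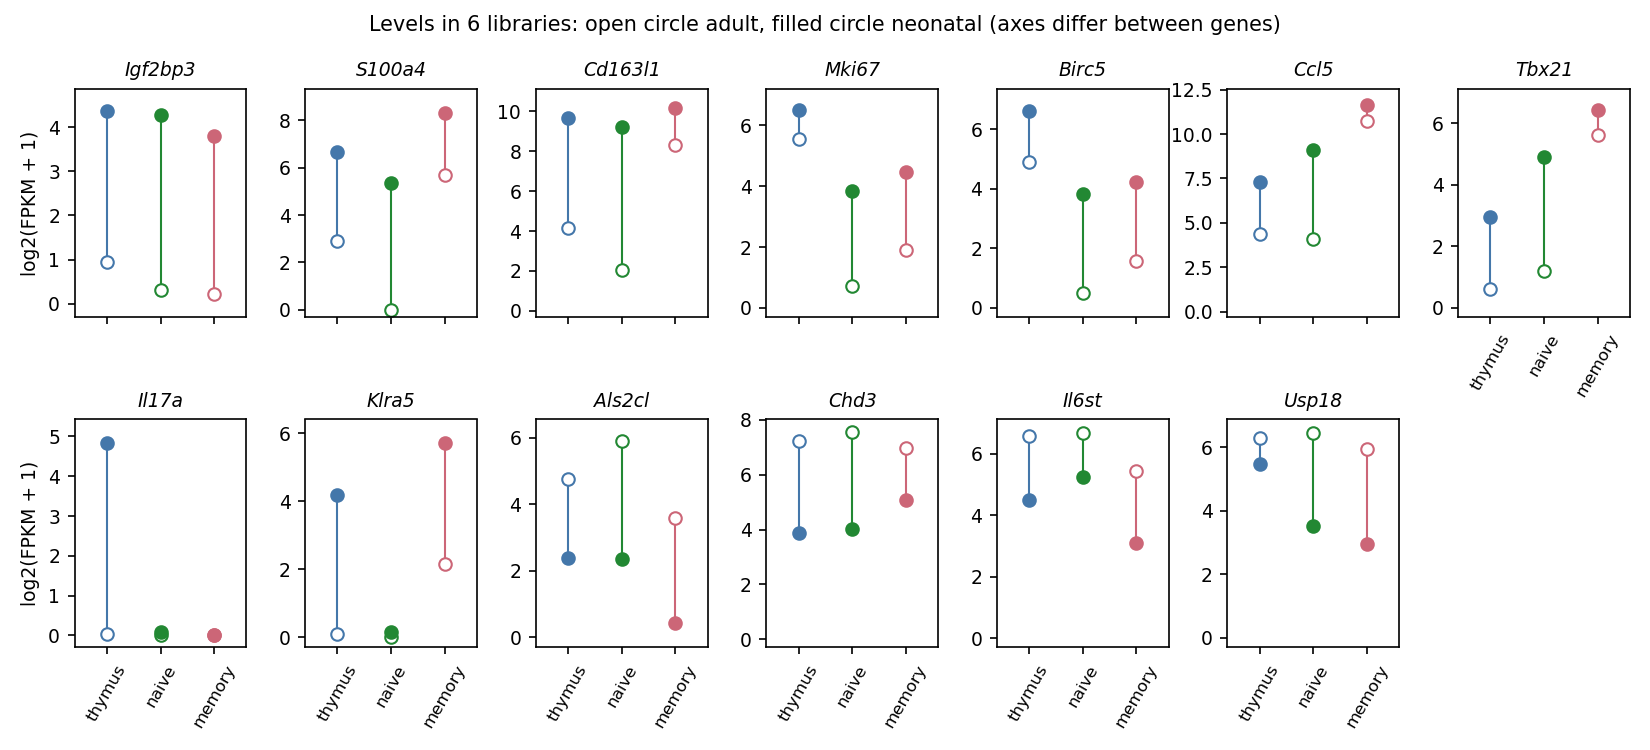
Expression of 13 named genes as log2(FPKM + 1) in thymus, naive and innate memory cells, with open symbols for the adult and filled symbols for the neonatal library, 1 library each. Igf2bp3 was at 19.7, 18.4 and 12.9 FPKM in the neonatal libraries and under 1 FPKM in each adult library.

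Neonatal thymocytes had more mRNA than adult ones of genes on the natural killer and gamma-delta T cell marker list (8 of 9 higher by size), to which the cytokine gene Il17a belongs. Of 22 genes on that list, 9 reached FPKM 5 in at least 1 of the libraries. Those that did so in the neonatal library alone, such as Il17a and Blk, could not count as lower. Il17a was at 0.0268 FPKM in the adult and 27.7 in the neonatal library, and Il17f at 0.532 and 47.7. Cd163l1, a marker of gamma-delta T cells, was at 16.6 and 815 FPKM, and the kinase gene Blk at 1.98 and 102. The granzyme genes Gzma (4.65 and 107 FPKM) and Gzmb (1.22 and 40.4) were also higher in the neonatal library. The remodeller Chd3 was lower, at 148 FPKM in the adult and 13.6 in the neonatal library, as were Itgae (141 and 46.9) and Id2 (123 and 27.4).

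By size, 723 of 8618 genes differed in thymus, 463 higher and 260 lower in the neonatal library. Scaled to TPM the split was 382 higher and 808 lower, with the median of all genes moving from 0.06 to -0.26, so the balance of directions depends on scaling. The authors' deposited table called 3111 genes, of which 625 also differed by size. The natural killer and gamma-delta list had a median of 3.30 (8 of 9 higher). Innate cytokine and killer receptors had a median of 2.22 (8 of 13 higher), memory T cell genes 1.61 (13 of 22 higher), cell cycle genes 1.07 (19 of 35 higher) and immediate early genes, such as Fosb and Fos, 0.85 (7 of 18 higher). Glycolysis genes, with Tpi1 and Gapdh highest, had a median of 0.53 (3 of 16 higher) and oxidative phosphorylation genes 0.52 (none of 27 past 2-fold), the latter against 0.03 to 0.50 in random lists. Naive T cell genes had a median of -0.59 (4 of 19 lower), exit and maturation genes -0.44, immature thymocyte genes -0.19 (2 higher and 2 lower of 21) and interferon-stimulated genes -0.21 (2 higher and 0 lower of 21), all outside their random lists. Within the range of random lists were fetal-type genes (0.16), cytotoxic genes (0.33, 5 of 13 higher) and transcription factors (-0.04, with a mean of 0.47 of opposite sign).

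Markers of other cells moved with age in the thymus as well. B cell markers had a median of 1.8 (5 of 6 higher), a list that includes Blk and the antigen-presentation genes H2-Aa (3.40 and 17.3 FPKM) and H2-Ab1 (3.81 and 16.1). Myeloid and dendritic cell markers had a median of 1.94 (4 of 5 higher), with C1qa at 1.15 and 9.47 FPKM. Blk, H2-Aa, H2-Ab1 and C1qa reach FPKM 5 in the neonatal library alone, so they could not count as lower. CD4 and regulatory T cell markers had a median of -1.54 (3 of 5 lower, including Folr4), and erythroid markers one of -0.24, within random lists. CD8 T cell identity genes had a median of -0.48, where random lists ranged from 0.17 to 0.64, with Cd5 at 268 FPKM in the adult and 107 in the neonatal library. Sex-linked genes had a median of -0.74 over 3 members.

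Neonatal naive cells, sorted for low CD44 and CD122, held more mRNA of memory T cell genes than adult naive cells and less of interferon-stimulated genes, by the medians of these lists. The chemokine Ccl5 was at 15.8 FPKM in adult and 539.6 in neonatal naive cells, Tbx21 at 1.30 and 29.2, the galectin Lgals1 at 37.0 and 352, and S100a6 at 1.16 and 67.2. S100a4 was listed at 0 in adult and at 39.3 FPKM in neonatal naive cells. Apart from small RNA genes, the largest positive difference was that of Cd163l1 (7.13), at 3.21 and 590.1 FPKM. Cd44 itself was at 3.13 and 6.00 FPKM and Il2rb, which encodes CD122, at 67.7 and 76.6. Klrc1, at 112 FPKM in neonatal innate memory cells, was at 0.962 in neonatal naive cells. In the other direction, the interferon response genes Usp18 (86.7 and 10.5 FPKM) and Iigp1 (27.1 and 0.00952) were lower in the neonatal library, as was Ly6a (83.7 and 7.27).

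By size, 554 of 8392 genes differed in naive cells, 295 higher and 259 lower. The balance turned at a minimum FPKM of 20 (98 and 143) and with a pseudocount of 5 (137 and 157). The authors' deposited table called 2083 genes, 456 of them also different by size. Interferon-stimulated genes had a median of -1.69 (20 of 25 lower; random lists -0.21 to 0.22). Member by member, their age difference in naive cells minus that in thymus had a median of -1.41, where random lists ranged from -0.23 to 0.21. Cell cycle genes had a median of 1.25 (12 of 23 higher, such as Mki67 and Stmn1), memory genes 0.74 (7 of 19 higher), fetal-type genes 0.33 (4 of 14 higher), oxidative phosphorylation genes 0.30 and immature thymocyte genes 0.26. Naive T cell genes (-0.59), exit and maturation genes (-0.53, 7 of 25 lower), and immediate early genes (-0.17) lay below their random lists. Cytotoxic genes (0.12), transcription factors (0.10), glycolysis genes (0.20), CD8 identity genes (-0.15) and CD4 markers (-0.28) lay within theirs. Innate receptors did as well at -0.12, with a mean of 0.17 of opposite sign. Natural killer and gamma-delta markers had a median of 0.45 over 3 members, and B cell, myeloid and erythroid markers had 2 members each at FPKM 5, too few for a median.

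Innate memory cells, sorted for high CD44 and CD122 at both ages, differed with age by size in 21 of 29 cell cycle genes and in 8 of 20 innate cytokine and killer receptors, 7 of them higher. The killer receptor genes Klra5 (3.50 FPKM in adult, 51.7 in neonatal cells), Klrb1c (4.66 and 39.6) and Klre1 (7.66 and 49.8) were higher in the neonatal library. So were the signalling adaptors Fcer1g (6.50 and 67.1 FPKM) and Tyrobp (5.55 and 39.7). Klra genes have close paralogs that share reads. Lower in the neonatal library were Igfbp4 (31.6 and 2.57 FPKM), Dapl1 (177 and 19.8), the lymph node homing receptor Ccr7 (143 and 33.1) and Prf1 (62.5 and 15.7). Cd44 (36.0 and 34.4 FPKM), Il2rb (464 and 383) and Eomes (76.7 and 84.5) differed less than 2-fold.

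By size, 475 of 8464 genes differed in innate memory cells, 249 higher and 226 lower (282 and 314 in TPM). The authors' deposited table called 2528 genes, 396 of them also different by size. Cell cycle genes had a median of 1.76 (21 of 29 higher), natural killer and gamma-delta markers 2.19 (6 of 8 higher), memory genes 0.87 (12 of 27 higher, such as S100a4 and Ccr2), innate receptors 0.52 (7 of 20 higher), oxidative phosphorylation genes 0.34 and fetal-type genes 0.23. Interferon-stimulated genes (-0.90, 12 of 24 lower), naive T cell genes (-0.71, 6 of 18 lower), exit and maturation genes (-0.69, 8 of 25 lower), B cell markers (-1.41, 4 of 5 lower) and CD8 identity genes (-0.16) lay below their random lists. Immediate early genes, at -0.10, lay just below theirs. Cytotoxic genes (0.12, 1 higher and 3 lower of 17), transcription factors (-0.02, mean 0.07), glycolysis genes (0.25), immature thymocyte genes (0.06), CD4 markers (-0.18, mean 0.05) and myeloid markers (-0.29, mean 0.43) lay within theirs. Sex-linked genes had a median of -0.47, and of -0.53 in naive cells.

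**Figure D2:**
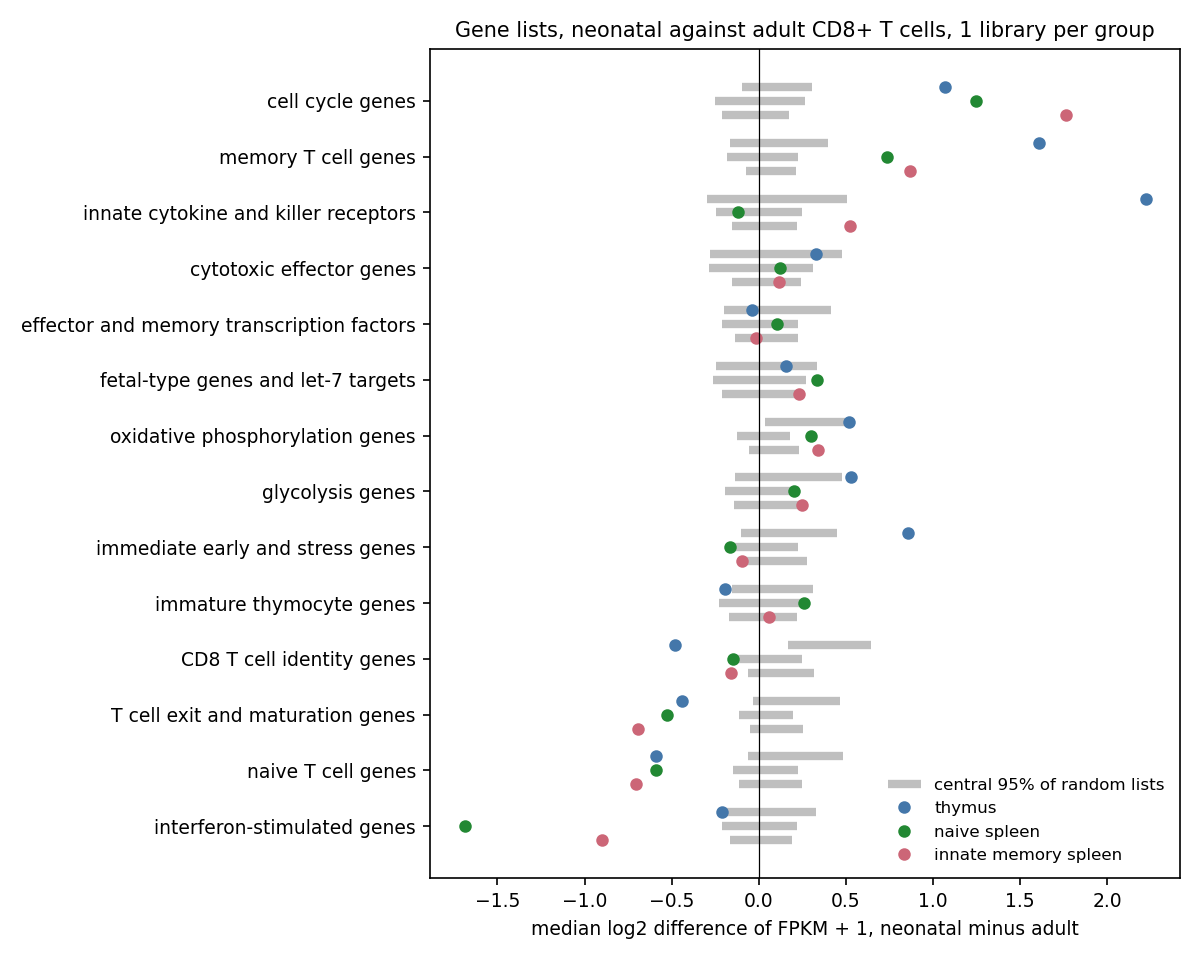
Median neonatal minus adult difference of log2(FPKM + 1) for 14 gene lists in thymus, naive and innate memory cells (points), with the central 95% of 10000 matched random lists (bars), from 1 library per group. Cell cycle genes lie above their random lists in each compartment (1.07, 1.25 and 1.76), and interferon-stimulated genes are lowest in naive cells (-1.69).

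Genes that mark innate memory cells in adults were higher in the neonatal thymus, in libraries that shared nothing with the definition. With small RNA genes left out, 237 genes were 2-fold or more higher in adult innate memory than adult naive cells. Of these, 145 were measured in thymus, and 72 of the measured genes were higher and 2 lower in the neonatal library. Their median was 0.99, where random lists ranged from -0.11 to 0.12. In naive cells the median was 1.04, biased upward because the adult naive library also defined the genes, and in innate memory cells it was 0.15, biased downward for the like reason. Defined in neonatal cells, likewise without small RNA genes (210 genes), the same readout in thymus had a median of 0.91. Markers of other cells were higher on both sides. Adult innate memory cells exceeded adult naive cells by medians of 1.68 for B cell, 2.00 for myeloid and 1.94 for natural killer and gamma-delta markers, and neonatal exceeded adult thymus by 1.8, 1.94 and 3.30.

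Innate memory cells of both ages had higher mRNA of memory T cell genes than naive cells of the same age, by the median of the list. The inhibitory receptor gene Klrc1 rose by 5.46 over both ages (SE 0.39, adjusted p = 0.0205 by limma), and the chemokine receptor Ccr2 by 4.21 (SE 0.42, adjusted p = 0.0359), each higher at 2 of 2 ages. The genes for the markers used in the sort rose too, Cd44 by 2.75 (SE 0.26, adjusted p = 0.0354) and Il2rb by 2.53 (SE 0.15, adjusted p = 0.0155). The gut-homing receptor Ccr9 fell by 3.52 (SE 0.23, adjusted p = 0.0165) and the integrin Itgae fell by 3.94 (SE 0.42, adjusted p = 0.0460). Ccl5 was at 15.8 FPKM in adult naive and 1674 in adult innate memory cells, yet did not pass across ages (4.60, adjusted p = 0.165), nor did Tbx21 (2.97, adjusted p = 0.192), Eomes (1.68, adjusted p = 0.337) or Gzma (3.35, adjusted p = 0.319).

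By size, 385 of 8411 genes differed between adult innate memory and naive cells (269 higher, 116 lower) and 337 of 8352 between the neonatal ones (240 higher, 97 lower; 233 and 217 in TPM). In TPM the median of all genes moved to -0.14 in adults and -0.20 in neonates. The authors' deposited table called 1664 genes in adults and 1469 in neonates, of which 294 and 263 also differed by size. Among the largest outside small RNA genes were, in adults, Ccl5 (6.64), Cd163l1, S100a6 and Samd3, and in neonates Klrc1 (5.85), Klre1, Klra5 and Itgax. Limma called 40 genes over both ages, 28 higher and 12 lower, but 9 with a pseudocount of 0.1 and 0 with no filter on low values (1784 at an unadjusted p under 0.05). Memory T cell genes had 10 of 27 higher, and 23 adjusted over the list alone, with medians of 3.11 in adults and 2.31 in neonates. Cytotoxic genes had 1 of 16 higher, Gzmm (3.25), and 11 adjusted over the list alone (medians 1.19 and 1.49). Innate receptors had 2 of 16 higher, and 10 higher with 1 lower adjusted over the list alone (1.72 and 2.19). Naive T cell genes had 2 of 20 lower, Ccr9 and Itgae, and 7 lower with 1 higher adjusted over the list alone (-0.33 and -0.70).

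Natural killer and gamma-delta markers had medians of 1.94 and 2.75, with 0 of 6 passing limma and 6 higher adjusted over the list alone and unadjusted. Transcription factors had medians of -0.02 (mean 0.76) and 0.30, and cell cycle genes 0.19 and 0.62. Immature thymocyte genes had medians of 0.23 (mean -0.03) and -0.05, the former turning to -0.37 with a minimum FPKM of 1. By limma 1 of 20 was lower, and 2 higher with 4 lower adjusted over the list alone. Interferon-stimulated genes had medians of -0.17 in adults and 0.44 in neonates, and immediate early genes 0.40 and 0.38. Adult innate memory cells also had higher B cell markers (median 1.68, 4 of 5 higher, with H2-Aa at 1.09 and 6.33 FPKM) and myeloid markers (2.00, 2 of 3 higher). Myeloid markers had a median of 1.05 in neonates as well (2 of 3 higher), and B cell markers had 2 members there at FPKM 5. By camera, 9 lists passed with a preset correlation, memory genes first (adjusted p = 1.37e-23), and none did with an estimated one, where memory genes had adjusted p = 0.326 with an estimated correlation. The latter setting had little power here as well.

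Naive spleen cells had less mRNA than thymocytes of the same age of cell cycle genes (33 of 34 by limma) and some immature thymocyte genes (10 of 20, with 1 higher), and more of some T cell exit and maturation genes (7 of 25). Stmn1 fell by 4.19 over both ages (SE 0.42, adjusted p = 0.0141 by limma), and Mki67 fell by 3.75 (SE 0.51, adjusted p = 0.0219), each lower at 2 of 2 ages. The phosphodiesterase Pde2a rose by 3.68 (SE 0.67, adjusted p = 0.0394) and the complement regulator Cd55 by 3.13 (SE 0.37, adjusted p = 0.0166). In neonates, some genes that were among the highest over adults in thymus were low in naive cells. Il17a was at 27.7 FPKM in thymus and 0.0539 in naive cells, and Blk at 102 and 1.08. Not so for Cd163l1, at 815 and 590 FPKM.

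By size, 743 of 8526 genes differed in adults, 323 higher and 420 lower in naive cells (276 and 817 in TPM, where the median of all genes moved to -0.19). At a minimum FPKM of 20 the balance turned, with 198 higher and 153 lower. In neonates 1028 of 8603 did, 344 higher and 684 lower. The authors' deposited table called 2487 and 3306 genes, of which 633 and 914 also differed by size. Limma called 727 genes, 241 higher and 486 lower, and 0 with no filter on low values (3128 at an unadjusted p under 0.05). Cell cycle genes had 33 of 34 lower, and 34 adjusted over the list alone (medians -2.63 in adults and -2.39 in neonates). Immature thymocyte genes had 10 of 20 lower and 1 higher, and 11 lower with 1 higher adjusted over the list alone (-1.42 and -1.02), with Myb, Cd24a and Sox4 lower. Exit and maturation genes had 7 of 25 higher, and 14 adjusted over the list alone (0.97 and 0.63). Naive T cell genes had 4 of 20 higher and 1 lower, and 6 higher with 1 lower adjusted over the list alone (0.11 and 0.49). Interferon-stimulated genes had medians of 0.60 in adults and -0.86 in neonates, and 0 of 25 passed limma over all genes or adjusted over the list alone, with 2 higher and 2 lower unadjusted. Immediate early genes had medians of 1.15 and 0.16, innate receptors 0.83 over 9 members and -0.62 over 14, and natural killer and gamma-delta markers 0.39 and -2.97. Cytotoxic genes in neonates had a median of 0.33 and a mean of -0.73, and the median turned to -0.048 with a minimum FPKM of 1. By camera, cell cycle genes came first with a preset correlation (adjusted p = 5.16e-27), and none of the lists passed with an estimated one (smallest adjusted p = 0.442 with an estimated correlation). Again the latter setting had little power.

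In adult splenic CD8+ T cells with induced Lin28b, mature let-7, the miRNA family whose processing Lin28b blocks, took 6.16% of miRNA reads against 44.1% in control cells. The family was 7.17-fold lower in iLin28b (95% counting interval 7.11 to 7.22), a log2 ratio of -2.84. That ratio was -2.25 without the 3 most abundant miRNAs and -3.69 without let-7c-5p. The share was 5.42% and 6.76% in the A and B columns of iLin28b and 44.2% and 44.1% in those of control. Of 10 guide strands, 9 were lower, from let-7d-5p (-4.88), let-7b-5p (-4.69) and let-7i-5p (-4.50) to let-7a-5p (-2.87) and let-7e-5p (-2.50). The most abundant, let-7f-5p, was at 168827 RPM in control and 12286 in iLin28b (-3.78). Between them lay let-7j (-3.95), let-7g-5p (-3.77) and miR-98-5p (-3.47). The exception was let-7c-5p, at 19485 RPM in control and 28816 in iLin28b, a log2 ratio of 0.56 (0.53 to 0.59; 0.20 to 0.82 over the 4 pairings). That ratio was 0.06 with the median ratio of all miRNAs set to 1. Of the other arms, let-7d-3p was lower by a log2 ratio of -5.83.

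**Figure D3:**
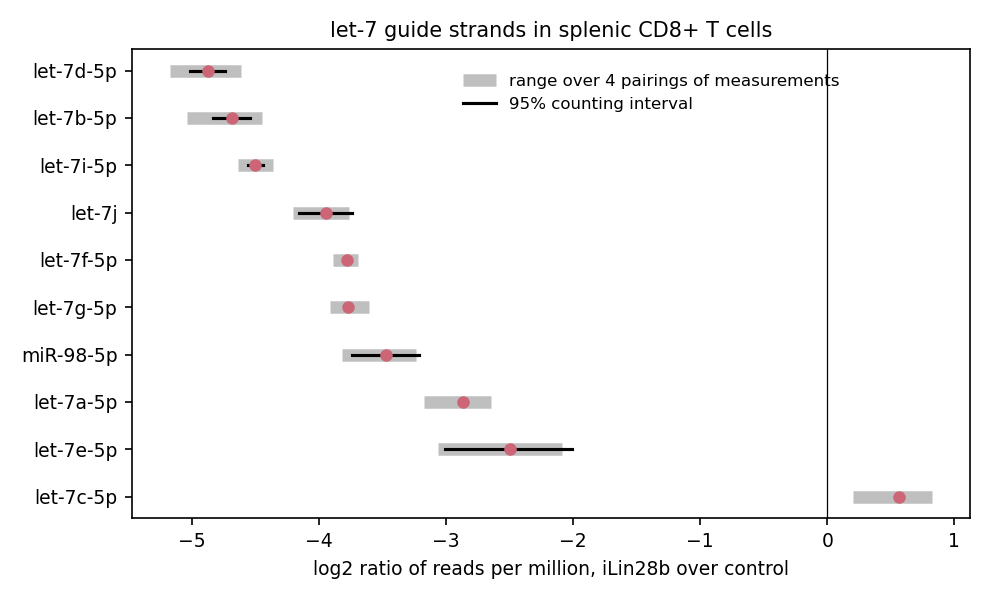
Log2 ratio of RPM, iLin28b over control, for 10 let-7 guide strands, with the 95% counting interval and the range over the 4 pairings of A and B columns. The ratio is below -2 for 9 guides in the summed columns (-4.88 to -2.50), and let-7c-5p is at 0.56.

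Outside let-7, the largest ratios were in miRNAs that were higher in iLin28b, among them miR-21a-5p, which is tied to T cell activation and held 7.13% of reads in control and 31.9% in iLin28b (log2 ratio 2.16). With miR-21a-5p stood miR-139-5p (2.48), miR-183-5p (2.25) and miR-504-5p (2.93). By size, 59 of 241 miRNAs were higher and 17 lower, 5 of the latter outside let-7, with miR-125a-5p (-1.39) the lowest of these. In all 4 pairings 31 were higher and 12 lower. The median miRNA stood at 0.50. With that median set to no change, 26 were higher and 27 lower, and without the 3 most abundant miRNAs 141 were higher and 10 lower, so the balance depends on scaling. T cell miRNAs had a median of 0.39 over 50 arms, -0.12 relative to all miRNAs, with 5 higher and 0 lower by size. The miR-17-92 cluster and its paralogs had one of 0.79 over 17 arms, 0.28 relative to all miRNAs, with 4 higher. The lymphocyte miRNA miR-150-5p was at -0.01, and its sign depends on scaling.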

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

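Apart from the count over other splits of the libraries, the tests in this part were chosen after the results they measure had been seen. The list medians below drew attention because they took opposite signs in compartments or ages, each outside the range of its random lists. With 1 library per group, the differences between those groups were not tested against variation between animals. Where members were shared, their differences were set beside random lists, which describes genes alone.

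Interferon-stimulated genes were higher in naive spleen than in thymus among adults (median log2 difference 0.60) and lower among neonates (-0.86). Member by member, the age difference in naive cells minus that in thymus had a median of -1.41 (random lists -0.23 to 0.21). Between innate memory and naive cells these genes had a median of -0.17 in adults and 0.44 in neonates, with 0.51 for the age difference in innate memory minus naive cells (random lists -0.14 to 0.13). Innate cytokine and killer receptors had a median of 0.83 for naive spleen against thymus in adults (9 members) and -0.62 in neonates (14 members). Over the 9 members measured in both, the age difference in naive cells minus that in thymus had a median of 0.11 (random lists -0.37 to 0.27). Receptors that reach FPKM 5 in thymus alone are not among the 9, so this value does not speak for them. For neonatal against adult cells, immediate early and stress genes had a median of 0.85 in thymus, -0.17 in naive cells and -0.10 in innate memory cells. Against thymus, members lay at a median of -0.94 in naive cells (random lists -0.31 to 0.13) and -0.77 in innate memory cells (-0.29 to 0.12). Immature thymocyte genes had a median of -0.19 in thymus and 0.26 in naive cells, with 0.71 for naive cells minus thymus (random lists -0.27 to 0.21). B cell markers had a median of 1.8 in thymus and -1.41 in innate memory cells, with -3.15 for innate memory cells minus thymus over 5 members (random lists -0.50 to 0.50). Members such as H2-Aa reach FPKM 5 in thymus through the neonatal library alone, so they could only be higher there. The opposite signs of this short list thus follow in part from the filter. No biological explanation was tested for these opposite signs, and age and compartment stay open for each.

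The age effect called 552 genes over the 6 libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the split by age itself, and the highest other split gave 2. In each other split the difference between adult and neonatal libraries enters the residual, and some splits part the libraries of 1 compartment only. Their low counts thus follow from the design and do not measure chance. The count was 341, 9 and 71 without the thymus, naive and innate memory compartments. With 10 splits the share cannot fall under 0.05.

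Memory T cell genes, and the genes that mark innate memory cells in adults, were higher in the neonatal than in the adult naive library. Innate memory cells carried over in the neonatal sort, which a gate for CD44low CD122low cells would reduce, would bring all their abundant transcripts in 1 share. Signature genes under FPKM 1 in adult naive cells (26 genes) called for a median share of 6.19% (SD of the median 2.05). Those at FPKM 1 or more (94 genes), not chosen on the age difference, called for 27.7% (SD 3.20). The adult naive library also defined the signature, so values low in it by chance raise the share called for. That bias weighs more at FPKM 1 or more. The unlike shares therefore do not decide whether admixture was the whole cause for the signature. The 18 signature genes on the memory T cell list called for 7.27% (SD 2.35), and 10 of the 120 signature genes, 4 of them on the list, stood in neonatal naive cells under 0.5 of the level that this share alone would bring, with 6 under the level of this share less 2 SD. The 8 list genes under FPKM 1 in adult naive cells called for 4.65% (SD 2.00), for which these counts were 5 and 2, so admixture as the whole cause for that list may remain, and a difference of the naive cells with age stays open and was not tested.

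Il17a, Il17f, Blk and Sox13 were higher in the neonatal than in the adult thymus library. Admixed IL-17-type T cells are a candidate source, although depletion of CD4+ cells and sorting on CD8 would remove cells without CD8. Cd8a and Cd8b1 differed by -0.15 (log2) from the mean difference of the Cd3 genes (spread 0.35), a value that leaves this open because a small share would be hidden. Per unit of Cd163l1, Blk, Sox13, Il17a and Il23r were in neonatal naive cells a median of 0.01003 of the neonatal thymus value (highest 0.0397). Blk and Il17a had already been seen to be high in thymus and low in naive cells, so this outcome was largely set beforehand. The Cd163l1 mRNA of naive cells thus came with little of these genes, which does not decide whether it had 1 source in both. Reads of 5830411N06Rik, a neighbour of Cd163l1 in the same gene family, assigned to Cd163l1 in a fixed share are argued against by a ratio that ranged 39.2-fold over the 6 libraries. An effect of age itself stays open and untested.

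The let-7c-5p reads were not lower in iLin28b, unlike those of the other let-7 guides. Reads of let-7a-5p assigned to let-7c-5p in a fixed share are argued against, since let-7c-5p reads per let-7a-5p read were 10.8-fold higher in iLin28b (3.52) than in control (0.326). Scaling moves all miRNAs of a library alike, so it cannot make the distance of let-7c-5p from the highest other guide, 3.07 (log2). That holds by construction and does not bear on the direction of let-7c-5p itself. Its log2 ratio of 0.56 lay close to the median of all miRNAs, 0.50, so this direction depends on scaling. An unequal action of Lin28b on the let-7 precursors may be behind the distance and was not tested, and neither was a difference between the single samples.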

How the results depend on the processing

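Alternatives for naive spleen against thymus, those without small RNA genes and the let-7 family without let-7c-5p were chosen after seeing the data. The cause of each change below was not tested, except where fewer or more genes or libraries enter by construction.

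By size, a pseudocount of 5 gave 409 genes for age in thymus, 294 in naive cells and 254 in innate memory cells, 251 for adult innate memory against naive, 486 and 644 for adult and neonatal naive spleen against thymus, and 42 shared by the 3 compartments. A minimum FPKM of 20 leaves fewer genes by construction and gave 364, 241 and 215 for age in the same order, 186 for innate memory against naive at either age, and 351 and 542 for naive spleen against thymus. With a minimum FPKM of 1 or no filter, age in naive cells gave 909 genes and adult innate memory against naive 631. With a minimum FPKM of 1, 171 genes were shared by the 3 compartments and the adult memory signature had a median of 0.82 in thymus. TPM gave 1190 genes for age in thymus. Genes shared by the remaining pair of compartments numbered 215 without the thymus, 147 without the naive and 174 without the innate memory compartment.

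Limma's age effect called 348 genes without a trend, 341 without the thymus, 9 without the naive and 71 without the innate memory compartment, the last 3 with 4 libraries each. With a pseudocount of 0.1 the innate memory effect called 9 genes. With no filter on low values limma called 0 genes for age (3082 at an unadjusted p under 0.05), 0 for innate memory (1784) and 0 for naive spleen against thymus (3128). Without small RNA genes the counts were 805, 45 and 885.

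With a minimum FPKM of 1, the median of immature thymocyte genes for adult innate memory against naive reversed to -0.37 (0.23 as reported), and that of cytotoxic effector genes for neonatal naive spleen against thymus to -0.048 (0.33 as reported). The other gene list medians kept their sign where it was called, 374 of 390 within their spread and 14 beyond it.

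The let-7 family had a log2 ratio of -3.35 with the median ratio set to 1, -2.25 without the 3 most abundant miRNAs, -2.68 with the authors' RPM, -2.46 summed over precursor entries and -3.69 without let-7c-5p. The count of miRNAs by size was 151 without the 3 most abundant, 146 with a minimum of 10 reads and 36 with one of 500. Of 364 values of single miRNAs, 134 stayed within their counting interval and 230 left it. Of 2536 values of single genes, 2430 stayed on the same side of 2-fold and 106 crossed it.

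The alternatives set out for the bulk spleen results were not run. Depth is not known for the mRNA libraries, so how far counting error limits genes near FPKM 5 could not be computed.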

Other observations

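The most abundant gene of the 3 adult libraries was Mir703, at FPKM 7445 in thymus, 12140 in naive cells and 11380 in innate memory cells. In the 3 neonatal libraries it was Eef1a1. The 1199 genes for small RNAs took 3.72%, 4.96% and 4.25% of FPKM in the adult thymus, naive and innate memory libraries and 2.65%, 3.24% and 2.95% in the neonatal ones. FPKM of genes this short depends strongly on fragment length.

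The precursor-level table lists let-7a-1-3p and let-7c-2-3p with identical reads, 205 in iLin28b and 249 in control, so these arms share 1 measurement.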
